A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

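Dye-swap data from 4 arrays on an slt2 mutant of Saccharomyces cerevisiae, treated with zymolyase 100T or left untreated, were taken as 1 group of 4 two-colour arrays, numbered as in their titles. Per the labels' protocols, RNA was extracted with a column kit and labelled directly with Cy5-dUTP and Cy3-dUTP. The deposited values are log ratios between both channels of an array, treated here as log2 by their size, since the labels do not state the base. The numerator, the background correction, the normalization and the filter that left spots without a value are not given in the sources used here. Scanner intensities were not used here, so signal over background is unknown. The medians of the deposited values were -0.02, 0.05, -0.10 and 0.02 on arrays 1 to 4 and their SDs 0.36, 0.45, 0.64 and 0.63. No centring or scaling was added. Scale, centring and direction as the authors set them stay unknown.

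The table held 6209 rows, 1 per reading frame, and 2 control spots were left out. Row names were matched to locus tags of the RefSeq gene table of assembly R64, used for names, neighbours and coding lengths. Of 6207 reading frames 5675 matched, 21 of them through a synonym held by 1 gene, and 532 kept the table's name. The match through synonyms was added after first results had been seen, when DDR2 appeared among the largest changes under an old name. A gene was tested if all 4 arrays held a value, which 4788 did, 4576 of them matched. A further 787 had a value on 1 to 3 arrays and 632 on none. What the spots are made of is not given in the sources used here, so overlapping, antisense and near-identical genes cannot be told apart with certainty.

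The sign rule was set on the correlations between arrays alone: since all pairs of opposite dye orientation correlated below 0, the values were read as dye ratios and arrays 1 and 3 were turned. Which side is higher with zymolyase follows from the unstated numerator, and only sizes and sides were reported. The arrays of a culture were averaged, so that the fit rested on 2 cultures. As the labels do not tie arrays to cultures, limma (version 3.58.1, R 4.3.3) was fitted with lmFit and eBayes for both possible pairings, arrays 1 with 2 and 3 with 4, and arrays 1 with 4 and 2 with 3. Each gene took the larger p, and these were adjusted by the Benjamini-Hochberg method, with calls at an adjusted p under 0.05. The prior degrees of freedom were infinite for the first pairing, which gives every gene the same variance there (0.119) and a standard error of 0.24, and 10.0 for the second. A gene with 1 extreme array can therefore be called. Treated and untreated RNA came from the same culture on each array, and SDs are over the 4 arrays, which mix cultures and dyes.

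Gene lists were tested with camera from limma with a preset correlation of 0.01, again with the larger p of both pairings, adjusted over the 34 lists of at least 5 measured members. The alternative with an estimated correlation took the 4 arrays without averaging by culture, and its test rests on their few residual degrees of freedom. The 36 lists were written from general knowledge and fixed before the data were examined, as were the tests, the sign rule and the rule for named genes. That rule took SLT2 first. It then took the 12 largest mean changes on each side among called genes with the same sign on all 4 arrays, filled where fewer were called with genes whose smallest size over the arrays was largest. From each list described it took up to 4 members with the largest mean change and the same sign on all arrays. GPD1 and the genes said to be named after their values were seen fall outside it. Where a list's name and its leading members differ, the members were named. The ribosomal protein list was taken by a rule on gene names, and so also holds RPP1, a ribonuclease P subunit gene. Median and camera side differed for the chitin, heat shock, glycolysis and ergosterol lists, all with medians under 0.05.

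The fit and the list test were tested on simulated data for the 4788 genes, with 200 genes changed. Of genes changed 2-fold, 85.0% were recovered, and of genes changed 4-fold, 99.0%, while 3.66% of calls were unchanged genes. The simulation drew each gene's spread independently of its change and held no length trend and no correlation between genes. It therefore does not test camera on lists of correlated genes, such as ribosome biogenesis with an estimated correlation of 0.36. Alternatives covered each pairing alone, 4 arrays as separate replicates, a random culture block, a dye term, median centring, scaling to equal median absolute deviation, genes with a value on at least 3 arrays, robust variance moderation, fold minimums of 2 and 1.5, unturned arrays, rank-based camera, camera with an estimated correlation, Spearman correlation and leaving out each array. Added after seeing the data were the removal of a loess trend with coding length on each array, arrays 1 and 2 or arrays 3 and 4 alone, genes with a RefSeq match alone, and the same sign on all 4 arrays. Coding lengths are spans from start to stop in the RefSeq gene table with introns included, since it gives no exons. They covered 95.6% of tested genes, and 96.6% were multiples of 3; for ribosomal protein genes 53 of 133 were not, so their spans exceed their coding sequence. The trend was also removed over genes whose span is a multiple of 3 alone, which leaves out many, not all, genes with introns.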

Results

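Budding yeast (Saccharomyces cerevisiae) lacking a working SLT2 gene was exposed to zymolyase 100T, an enzyme preparation that digests the glucan of the cell wall. SLT2 encodes the mitogen-activated protein kinase at the end of the cell wall integrity pathway. A culture in rich glucose medium was split, 1 part received zymolyase at 5 units per ml, and RNA was collected from both parts after 3 h. RNA of 2 cultures was labelled with Cy3 and Cy5 and hybridised to 4 DNA microarrays with the dyes swapped. The treated part carried Cy3 on arrays 1 and 3 and Cy5 on arrays 2 and 4. The labels do not say which 2 arrays share a culture. On array 3 the source label of the treated channel reads wild type, while the title, the other channel and the series name the slt2 mutant. Arrays 1 to 4 held a value for 5402, 5434, 5201 and 4931 of 6207 reading frames, and 4788 had one on all 4 arrays. The number of arrays limits the precision of every value.

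The deposited log ratios of arrays with opposite dye orientation correlated below 0 across genes (r from -0.60 to -0.29), so arrays 1 and 3 were turned. Neither the labels nor the deposited table states which dye is the numerator, and the direction of every change therefore stays open. If the ratio is Cy5 over Cy3, the stress genes below were lower with zymolyase. If it is Cy3 over Cy5, channel 2 over channel 1, they were higher, the reading that general knowledge of zymolyase as an activator of stress-responsive kinase pathways would favour, while the values and labels decide neither. Changes are given as sizes on 2 opposite sides, the HSP12 side and the TIP1 side, each named after a called gene. The base of the logarithm was not stated and was taken as 2, and folds assume it. SLT2 (YHR030C) had a value on 0 of the 4 arrays, so the deleted gene could not serve as a check of the labels, including that of array 3.

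After turning, every pair of arrays correlated above 0 across genes, with a mean r of 0.459. For pairs of opposite dye orientation the sign was fixed in advance, since their correlations decided the turning. The pair of arrays 3 and 4 had an r of 0.60 and the pair of arrays 1 and 2 an r of 0.54. The pairs of the same dye orientation had 0.49 (arrays 1 and 3) and 0.52 (arrays 2 and 4). Arrays 1 and 4 (0.29) and arrays 2 and 3 (0.31) were least alike. As Spearman's rho, these had 0.15 and 0.09, and arrays 3 and 4 had 0.50. Arrays 1 and 2 had a rho of 0.24, below arrays 1 and 3 (0.43) and arrays 2 and 4 (0.42). Genes are not independent replicates, and no p-value was attached to these correlations. The mean of the 4 turned arrays held 57.8% of the variance over genes, the dye component 15.0%, and the contrast of arrays 3 and 4 with arrays 1 and 2 21.0%. A change on some arrays alone also enters that mean, so the 57.8% need not be common to all 4 arrays. Of the 4788 tested genes, 30.3% lay on the same side on all 4 arrays, where independent signs give 12.5%. Arrays of 1 culture need not have independent signs, so 12.5% may be too low a reference.

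The question of the experiment was how transcript levels respond to cell wall digestion when Slt2 is missing. The stress genes CTT1 and HSP12 lay together on 1 side, with sizes of 7.17-fold and 6.18-fold, and the opposite side held few and small changes. In all 218 genes changed, 208 on the HSP12 side and 10 on the TIP1 side (limma, adjusted p under 0.05, n = 4 arrays of 2 cultures). Of these, 133 on the HSP12 side and 3 on the TIP1 side changed at least 2-fold, and 26 and 0 at least 4-fold. At an unadjusted p under 0.05 there were 551 genes. On all 4 arrays 173 of the 208 and 9 of the 10 kept their side. Without array 1 the count was 76, without array 2 105 and without array 4 143. With arrays paired as 1 with 4 and 2 with 3 alone, the same model called 1415 genes, 49.1% of them on the HSP12 side. The arrays paired there had a consensus correlation of -0.667, against 0.122 in the other pairing, and the variance shared among genes in the model was 0.0224 against 0.119.

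Among the 12 largest changes on the HSP12 side were genes of the stress response with similar values on the 4 arrays. NQM1 (YGR043C), a transaldolase paralogue, had a log2 size of 3.58 ± 0.55 (SD, n = 4) (adjusted p = 4e-07). CTT1 (YGR088W), the cytosolic catalase, reached 2.84 ± 0.58, and HSP12 (YFL014W), a small membrane-associated heat shock protein gene, 2.63 ± 0.58. FMP45 (YDL222C), encoding an eisosome-associated membrane protein, had a size of 2.88 ± 0.79, MSC1 (YML128C) 2.74 ± 0.65 and RTN2 (YDL204W), a reticulon, 2.61 ± 0.50. RTC3 (YHR087W) had the largest mean, 4.56 ± 2.39, with 7.97 on array 2 and between 2.47 and 4.17 on the others, and means of 3.42 without array 2 and 5.25 without array 4. DDR2 (YOL052C-A, under its synonym YOL053C-A in the table) had a mean of 3.92 ± 3.46, with 9.10 on array 2 and a mean of 2.20 over the other 3 arrays, against 4.63 without array 3. Its adjusted p was 0.0936 without array 1.

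The other 4 genes of the 12 had their largest value on array 3. HAC1 (YFL031W), encoding the transcription factor of the unfolded protein response, had sizes of 0.16, 0.56, 8.63 and 2.72 on arrays 1 to 4, and a mean of 1.14 over arrays 1, 2 and 4. The retrotransposon Gag frames YMR046C (2.90 ± 3.42) and YBR012W-A (2.72 ± 3.32), nested in longer frames of near-identical repeated elements, had their largest values on array 3 (7.92 for YMR046C) and at most 0.86 on arrays 1 and 2. Over arrays 1, 2 and 4 their means were 1.23 and 1.09. YLR162W (2.79 ± 2.40) had sizes of 0.32, 2.09, 6.07 and 2.69 on arrays 1 to 4, and a mean of 1.70 without array 3. Without array 1 or without array 2 the means of HAC1 and the Gag frames were 3.39 to 3.97, and without array 1 that of YLR162W was 3.62. These 4 were called (adjusted p from 0.000957 to 0.00231) although their SDs were 2.40 to 3.91, because the model's standard errors, which draw on all genes, were at most 0.49. HAC1 and both Gag frames lost the call without array 1, 2 or 4 (adjusted p from 0.0695 to 0.256), and YLR162W without array 2 or 4 (0.0975 and 0.197).

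**Figure D1:**
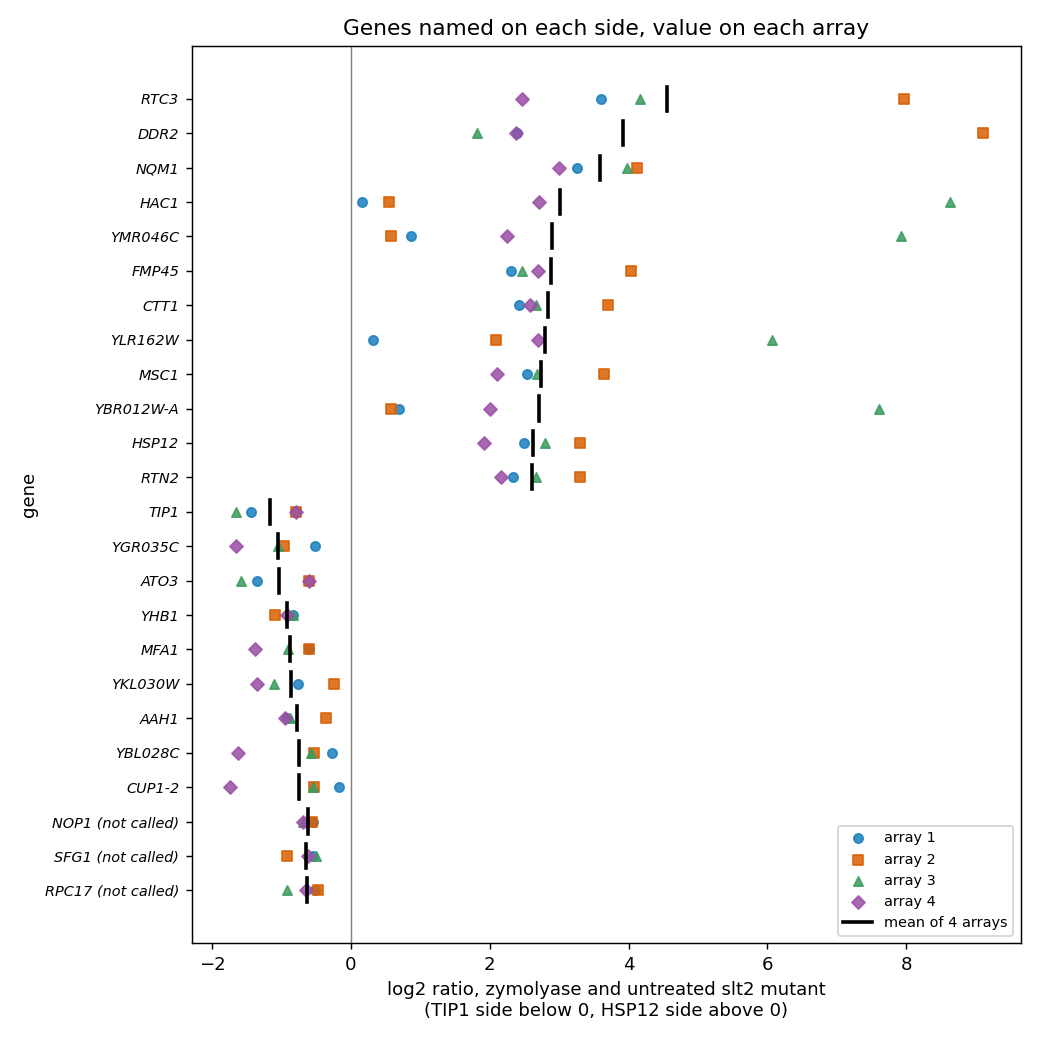
Log2 ratio between zymolyase-treated and untreated slt2 mutant on each of the 4 arrays (x axis, log2; HSP12 side above 0, TIP1 side below 0) for the 12 genes named on each side (y axis), with points for arrays and a black bar for their mean. NQM1 spans 2.99 to 4.12 and HSP12 1.91 to 3.30, while HAC1 spans 0.16 to 8.63. YHB1 on the TIP1 side lies between 0.83 and 1.09.

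Genes induced by high osmolarity and by general stress were the gene lists furthest on the HSP12 side. Of 20 measured members of the high osmolarity list, 20 lay on that side and 17 changed (18 when adjusted over the list alone), with a median size of 1.65, or 3.13-fold. The general stress list had 29 of 35 changed (30 adjusted over the list alone), with a median of 2.83-fold. The lists share 7 measured members, among them CTT1 and HSP12. Both passed camera with a preset correlation (adjusted p = 5e-23 and 6.18e-31), and both missed the threshold with an estimated correlation (adjusted p = 0.121 each with an estimated correlation). That run took the 4 arrays without averaging by culture and had few degrees of freedom. The list of autophagy and vacuolar proteases missed it too, with a negative estimated correlation (-0.03). The hexose transporter list also had a negative value (-0.08). A miss there therefore does not measure correlation within a list alone. The high osmolarity and general stress lists had estimated correlations of 0.35 and 0.11, above the preset 0.01. Their p-values with the preset correlation may therefore be too small. Without array 1 the general stress list had 18 members changed.

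Enzymes of reserve carbohydrate metabolism lay on the same side. Of 16 measured members of the trehalose and glycogen list, 8 changed (9 adjusted over the list alone), and the median size was 0.80. All 8 except UGP1 are also members of the general stress list, so the 2 lists are not independent. TPS2 (YDR074W), trehalose phosphate phosphatase, had a size of 2.27 ± 1.35 (SD, n = 4) and TSL1 (YML100W), a regulatory subunit of the trehalose synthase complex, 2.05 ± 0.08. PGM2 (YMR105C), phosphoglucomutase, reached 1.96 ± 0.36 and GPH1 (YPR160W), glycogen phosphorylase, 1.71 ± 0.14, so members that make and members that break down the reserves lay together. The list passed camera (adjusted p = 5.39e-10; adjusted p = 0.121 with an estimated correlation). TPS2 had 4.20 on array 3 and a mean of 1.62 over the other 3 arrays, and lost its call without array 1 (adjusted p = 0.0585). Without that array the list had 5 members changed.

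Vacuolar hydrolases and 1 glucose transporter were also on the HSP12 side. In the list of autophagy and vacuolar proteases 5 of 15 measured members changed (6 adjusted over the list alone), with a median size of 0.45 (camera adjusted p = 2.52e-05; adjusted p = 0.121 with an estimated correlation). The protease genes PRB1 (YEL060C; 1.81 ± 0.35) and APE1 (YKL103C; 1.24 ± 0.29), the mannosidase gene AMS1 (YGL156W; 0.80 ± 0.30) and the protease gene PEP4 (YPL154C; 0.77 ± 0.05) changed with the same side on all 4 arrays. The other called member, the carboxypeptidase gene CPS1 (1.06 ± 1.29), named after its values were seen, lay on the opposite side on array 3. All 5 encode hydrolases, and PRB1, AMS1 and PEP4 are also members of the general stress list. The count was 3 without array 1, and 2 without array 2 or without array 4. PEP4 lost its call whenever any 1 array was left out (adjusted p from 0.0512 to 0.151), AMS1 without array 1, 2 or 4 (0.0821 to 0.189), and CPS1 without array 2 or 4 (0.512 and 0.753). Among 7 measured members of the hexose transporter list, HXT1 (YHR094C), a low-affinity glucose transporter, changed with a size of 1.86 ± 0.27. The 3 members on the TIP1 side were HXT3, HXT4 and the glucose sensor gene SNF3 (-0.13, -0.05 and -0.09 toward the HSP12 side). HXT6, HXT7 and HXT2 had 0.65, 0.61 and 0.57 and did not pass over all genes, although 4 members passed when adjusted over the list alone. HXT6 and HXT7 are near-identical and their spots cannot be told apart with certainty. The transporter list had a median of 0.57 (camera adjusted p = 0.0320), and missed the threshold with an estimated correlation (adjusted p = 0.246 with an estimated correlation), with rank-based camera (adjusted p = 0.0833) and without array 1 (adjusted p = 0.0697). HXT6 passed without array 4 (adjusted p = 0.0344) and after centring each array on its median (0.0497).

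Targets of the cell wall integrity pathway lay on the HSP12 side in 21 of 23 measured cases, and 6 changed (9 adjusted over the list alone). The mutant lacks the pathway's kinase, but the arrays hold no wild type group and the direction stays open. Whether these changes depend on Slt2 was therefore not tested. Of members named after their values were seen, PRM5 and PST1 had 0.08 and 0.12 without a call. SED1, a called member, lay on the opposite side on array 3 (-0.43). The median size was 0.42, below that of the stress lists. CWP1 (YKL096W), a cell wall mannoprotein, had 1.83 ± 0.51 (SD, n = 4), PUN1 (YLR414C), a plasma membrane protein, 1.59 ± 0.58, and YPS1 (YLR120C), a cell surface aspartic protease, 1.48 ± 0.44. NCW2 (YLR194C), a wall protein, had 0.92 ± 0.16, and lost its call without array 1 or 2 (adjusted p = 0.0670 and 0.0544). The list passed camera (adjusted p = 1.87e-07; adjusted p = 0.121 with an estimated correlation), and 3 members changed without array 1 or without array 2. Of 26 members of the glucan and mannan synthesis list, OCH1 (YGL038C), a mannosyltransferase (1.02 ± 0.12), and CRH1 (YGR189C), a glucan and chitin transglycosylase (0.81 ± 0.38), changed, and 5 passed adjusted over the list alone. OCH1 lost its call without array 1 (adjusted p = 0.0537) and CRH1 whenever any 1 array was left out. EXG1 and KRE6 had 0.65 and 0.64 and were not called. That list did not pass camera (adjusted p = 0.0768), nor did the 11 measured genes of chitin metabolism (adjusted p = 0.677), of which 0 changed and 1 passed adjusted over the list alone.

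**Figure D2:**
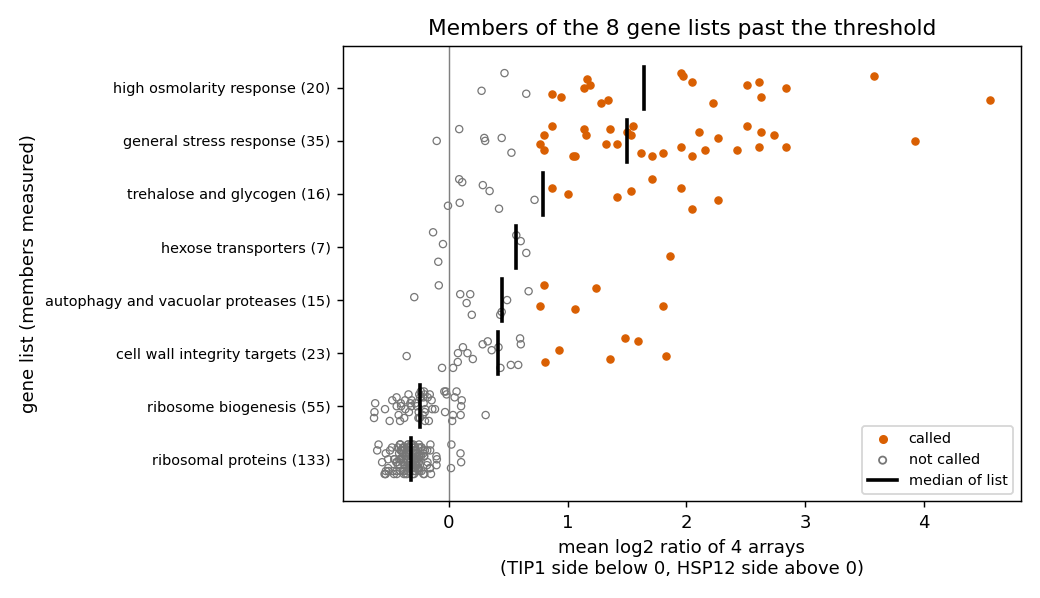
Mean log2 ratio over the 4 arrays (x axis, log2; HSP12 side above 0, TIP1 side below 0) of each measured member of the 8 gene lists past the threshold with a preset correlation (y axis, members measured in brackets); filled points were called, open points were not, and the bar is the list's median. Medians reach 1.65 for the high osmolarity list on the HSP12 side, and 0.32 on the TIP1 side for ribosomal proteins, of which 0 were called.

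On the TIP1 side the changes were small. TIP1 (YBR067C), a cell wall mannoprotein, had 1.17 ± 0.45 (SD, n = 4; 2.25-fold, adjusted p = 9.63e-05), YGR035C 1.05 ± 0.47, and ATO3 (YDR384C), a plasma membrane protein linked to ammonium export, 1.04 ± 0.51. YHB1 (YGR234W), flavohaemoglobin, had 0.91 ± 0.12, MFA1 (YDR461W), an a-factor precursor gene, 0.87 ± 0.37, and AAH1 (YNL141W), adenine deaminase, 0.78 ± 0.28. YKL030W (0.86), YBL028C (0.75) and the metallothionein gene CUP1-2 (0.75), whose spot cannot be told from CUP1-1, were also called. NOP1, SFG1 and RPC17, with sizes of 0.62, 0.64 and 0.64 and the same side on all 4 arrays, were not called. The count on this side was 10, and 1 without array 1, 4 without array 2 and 22 without array 3. Without array 1, TIP1, ATO3, YHB1, MFA1, YKL030W, AAH1, YBL028C and CUP1-2 lost the call (adjusted p from 0.0757 to 0.347). YGR035C, YHB1, MFA1, YBL028C and CUP1-2 lost it without array 2, ATO3 and AAH1 without array 3, and MFA1, YBL028C and CUP1-2 without array 4. YBL028C and CUP1-2 also lost it after centring each array on its median.

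Genes of the translation machinery lay slightly on the TIP1 side as a group. Of 133 measured members of the cytosolic ribosomal protein list, which also holds RPP1, 129 lay on that side with a median size of 0.32. One by one 0 changed (limma), also when adjusted over the list alone. The median over all 4788 tested genes lay 0.06 on the same side, and with the trend of coding length removed the median of the list was 0.20. RPS21A had 0.60, RPS29B 0.56, RPL19B 0.54 and RPL39 0.53. Many of these genes have a near-identical copy. Ribosome biogenesis genes were on the TIP1 side in 47 of 55 cases, with a median of 0.24 and 0 changed. NOP15 and KRR1 had 0.63, and IMP3 0.54. Both lists passed camera with a preset correlation (adjusted p = 7.74e-10 and 0.00104) and neither passed with an estimated one (adjusted p = 0.402 and 0.562 with an estimated correlation). The estimated correlations were 0.27 and 0.36, above the preset 0.01, so the p-values with the preset correlation may be too small. Without array 2 the biogenesis list missed the threshold with the preset one as well (adjusted p = 0.356). Without array 3, KRR1 and NOP15 passed (adjusted p = 0.0373 and 0.00396), as did the ribosomal protein gene RPS10B (0.0190), named after its values were seen.

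Sizes on arrays 3 and 4 moved with the coding length of the gene, taken as the span from start to stop with any intron included. Toward the HSP12 side, Spearman's rho with coding length over 4576 genes was 0.45 on array 3 and 0.40 on array 4, against -0.01 on array 1 and -0.18 on array 2. The difference between arrays 3 and 4 and arrays 1 and 2 had a rho of 0.62. Genes called on the HSP12 side had a median coding length of 1451 bases and those on the TIP1 side 351, against 1218 over all. The median was 1503 for the general stress list and 799 for ribosomal protein genes, of which 53 of 133 had a span that is no multiple of 3, so that introns lengthen many of these values. With the trend removed on each array, an alternative chosen after seeing the data, 153 genes were called, 148 on the HSP12 side and 5 on the TIP1 side, and 131 of them were among the 218. Without genes matched through a synonym that count was 144, and with spans that are multiples of 3 alone it was 158. The 5 were TIP1, YGR035C, ATO3, YHB1 and AAH1. MFA1, YBL028C and CUP1-2 lost the call and had smaller sizes, 0.58, 0.55 and 0.50 against 0.87, 0.75 and 0.75. HAC1, YLR162W, CRH1, YMR046C and YBR012W-A lost the call with sizes that did not shrink, 3.11, 2.98, 0.81, 2.94 and 2.75 against 3.01, 2.79, 0.81, 2.90 and 2.72, while the prior degrees of freedom went from infinite to 5.28 for the pairing of arrays 1 with 2 and 3 with 4. The general stress and high osmolarity lists had 29 and 17 members changed. The median of the ribosomal protein genes was 0.20 on the TIP1 side, a value that rests in part on spans with introns. Over the 80 of them whose span is a multiple of 3 it went from 0.32 to 0.17, and over the other 53 from 0.32 to 0.21. The hexose transporter list missed the threshold (adjusted p = 0.100) with a median of 0.56, against 0.57 before, while 3 other lists passed, for a total of 10: the tricarboxylic acid cycle (adjusted p = 0.00696), sulfur and methionine (0.0405) and glucan and mannan synthesis (0.0416), each on the HSP12 side.

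**Figure D3:**
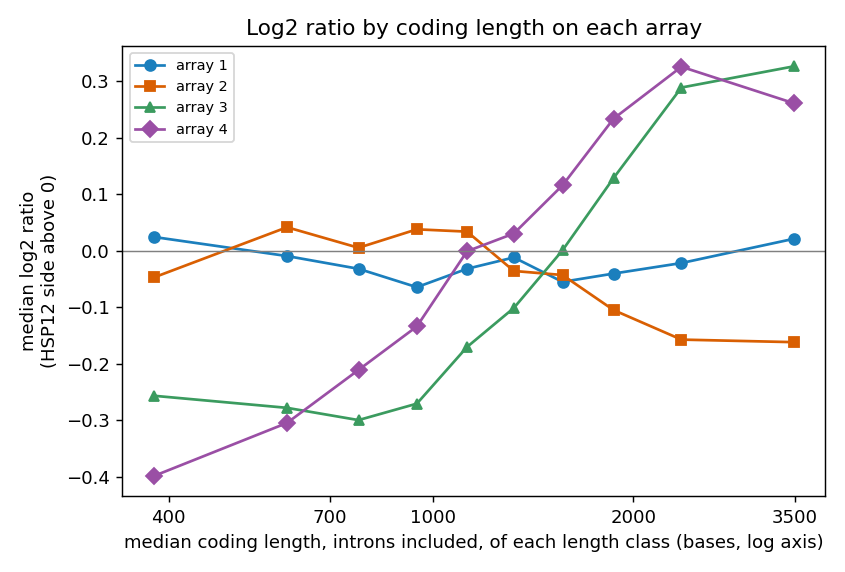
Median log2 ratio (y axis, log2; HSP12 side above 0) of 10 classes of genes ordered by coding length (x axis, median of the class in bases, log axis), 1 line per array. On arrays 3 and 4 the shortest class lies at -0.26 and -0.40 and the longest at 0.33 and 0.26, while array 1 stays between -0.06 and 0.02 in every class and array 2 lies at -0.16 in the longest.

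None of the other 26 tested lists passed camera with the preset correlation, although 3 of them passed once the length trend was removed and 6 with rank-based camera. Some also passed when 1 array was left out. Histones did so without array 1, and mitochondrial ribosomal proteins and sulfur and methionine without array 2. Glucan and mannan synthesis and the tricarboxylic acid cycle did so without array 2 or 4. Of 26 heat shock chaperone genes, 3 changed, all on the HSP12 side: SSE2 (1.10 ± 0.28), HSP26 (1.04 ± 0.49) and HSP42 (0.80 ± 0.34), and the list as a whole had a median of 0.00 (adjusted p = 0.626). Each of the 3 lost its call without array 1, HSP26 and HSP42 also without array 2, and HSP42 without array 4. MET3 (0.90 ± 0.25) and MET14 (0.86 ± 0.35) of sulfate assimilation were the 2 of 17 sulfur and methionine genes that changed (3 adjusted over the list alone; list adjusted p = 0.0871), and both lost the call without array 1 or without array 2, and MET14 also without array 3 (adjusted p = 0.118). FRE2, a ferric reductase (1.33 ± 0.10), and TIS11, an mRNA decay factor (1.51 ± 1.25), were the 2 of 17 in the iron regulon (0.145). TIS11 had 0.40 and 0.53 on arrays 1 and 2, and lost its call without array 1, 2 or 4. It also lost it with the length trend removed (adjusted p = 0.149), where its size was 1.62. PHO89, a phosphate transporter (1.20 ± 0.22), was the 1 of 14 in the phosphate starvation list (0.951). GRE2 (1.34 ± 0.31) and PRX1 (0.96 ± 0.57) were the 2 of 18 in the oxidative stress list (0.693). ALD6 (1.19 ± 0.11) and CAT2 (1.49 ± 0.96) were the 2 of 8 genes of gluconeogenesis and the glyoxylate cycle (0.464), and adjusted over the list alone 1 more passed, on the TIP1 side. PRX1 lost its call without array 1 or 2, and CAT2 without array 1, 2 or 4. With the length trend removed CAT2 had a size of 1.43 and an adjusted p of 0.0553. All these named genes lay on the HSP12 side.

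Lists of respiration, growth and the cell cycle held 0 changed genes, and adjusted over the list alone 1 member passed in each of the tricarboxylic acid cycle and daughter cell separation lists. Their camera adjusted p-values were 0.0871 for the tricarboxylic acid cycle, 0.693 for the respiratory chain, 0.951 for glycolysis and fermentation, 0.754 for amino acid synthesis, 0.0768 for mitochondrial ribosomal proteins and 0.951 for the proteasome. They were 0.951 for ergosterol synthesis, 0.210 for seripauperin and anaerobic wall genes, 0.116 for histones, 0.951 for G1 and S phase genes and 0.951 for G2 and M phase genes. They were 0.431 for daughter cell separation, in which CTS1 had 0.74 (adjusted p = 0.0502, and 0.0281 after centring each array on its median), and 0.951 for DNA damage. All 9 histone genes lay on the TIP1 side with a median of 0.25. Their list passed with rank-based camera (adjusted p = 0.0223) and without array 1, where the median was -0.38 toward the HSP12 side. The endoplasmic reticulum folding list had an adjusted p of 0.0768 and HAC1 as its 1 changed member.

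The lists of mating type and other cell state markers did not pass camera where tested. In the list of a cell genes, MFA1 changed, AGA2 and MFA2 had 0.60 and 0.42 on the TIP1 side without a call, and the list did not pass (camera adjusted p = 0.145). Adjusted over the list alone, 2 of its 6 members passed on the TIP1 side. With the length trend removed, MFA1 lost its call with a size of 0.58, and AGA2 and MFA2 had 0.39 and 0.13 on that side. The pheromone response list had 0 of 15 changed (0.299) and the filamentous growth list 1 of 7 (0.319; 2 adjusted over the list alone), namely MSB2 (1.03 ± 0.95), named after its values were seen. MSB2 had -0.12 and 0.65 on arrays 1 and 2 and 2.01 and 1.59 on arrays 3 and 4. It lost its call without array 1, 2 or 4 (adjusted p from 0.111 to 0.507), and with the length trend removed (0.143), where its size was 0.94. Of the alpha cell genes 1 was measured and of the sporulation genes 2, too few for a test, and 0 of these changed over all genes. The alpha cell gene, with a size of 0.61 on the TIP1 side, passed when adjusted over its list of 1. The strain marker genes HIS3, LEU2, URA3, LYS2, TRP1 and ADE2 had 0 changed (0.580), and MET17 had no value on any array.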

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

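The tests of coding length, of the ratio's direction and of the label of array 3 were chosen only after the results were seen; the count over sign patterns was set before its result was seen. Both tests of coding length replaced first versions that had been run. Of 67 named genes, 3 had 1 array far from the other 3, and about 3.35 are expected by chance. DDR2 had a size of 9.10 on array 2 and 1.82 to 2.40 on the others. CWP1 had 2.58 on array 2 and 1.49 to 1.63 on the others. AAH1 had 0.36 on array 2 and 0.88 to 0.95 on the others. Outside the 67, and so not part of the check, SED1 had -0.43 on array 3 and 1.88 to 2.01 on the others.

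The called members of the general stress and high osmolarity lists lay on 1 side, and which side is higher with zymolyase depends on the numerator. All 20 of 20 measured members of the high osmolarity list lay on the HSP12 side, but HSP12 is a member, and the count would be the same for either numerator. Cy3 over Cy5 and Cy5 over Cy3 cannot be told apart from these values, since SLT2, the transcript that would tell channels apart if 1 held wild type RNA, had a value on 0 arrays. No biological explanation was tested, because any direction of response depends on the numerator.

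The treated channel of array 3 carries a wild type label. If it held wild type RNA, the cell wall integrity targets might have lain further out than on array 4. The median of array 3 minus array 4 over the 23 targets was -0.10 toward the HSP12 side (95% bootstrap interval -0.33 to 0.19 over genes). SLT2 had no value on array 3, which excludes nothing, since an unstated filter left 632 reading frames without a value on any array. Because the size of a wild type response in these cultures is also unknown, a mistaken label and a mistaken sample cannot be told apart.

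A group of 55 called genes had a median size of 1.66 on arrays 3 and 4 and 0.26 on arrays 1 and 2, with a median coding length of 2319 bases. A trend with coding length on arrays 3 and 4 may be a source: after its removal the median difference between those pairs was 1.20 ± 0.89 (SD over genes), from 1.48 ± 0.81 before, but the genes were chosen for this difference, so what remains does not decide how much the trend explains. None of the 52 with a length stayed called: their median size was 0.94 ± 0.40 before and 0.94 ± 0.42 after, and the calls ended as the prior degrees of freedom went from infinite to 5.28 and the median standard error from 0.24 to 0.27. Of the 39 called members of the general stress and high osmolarity lists, 100% stayed called, so the trend is not the whole source there. For the 55 genes the trend, a difference between cultures, if arrays 3 and 4 share one, and one in RNA quality or labelling stay open.

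Turning the signs of the 4 arrays in the 8 possible patterns gave 218 genes for the real one and at most 6 for the others, and 1 pattern reached the real count. The real pattern, turned and not unturned, was picked from the correlations of these same arrays, so its higher count was in part built in. With 8 patterns no share under 0.05 can be reached.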

How the results depend on the processing

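The settings that remove the length trend (over all genes or over spans that are multiples of 3), leave out synonym matches, keep arrays 1 and 2 or 3 and 4 alone, keep RefSeq genes or require the same sign on 4 arrays were chosen after seeing the data. The count of 218 changed genes stayed within 1.5 times under most settings, with a share on the HSP12 side of at least 88.7%. The exceptions for the total, the HSP12 side and the TIP1 side were the pairing of arrays 1 with 4 and 2 with 3 alone (1415, 695 and 720; 49.1% on the HSP12 side), a 2-fold minimum with the same sign on 4 arrays and no test (120, 117 and 3), and arrays 3 and 4 alone (427, 348 and 79; 81.5%). Leaving out each array gave totals of 76 to 195, with 75 to 173 on the HSP12 side and 1 to 22 on the TIP1 side; a culture then rested on 1 array, assumed to vary like the means of the others. Unturned arrays gave 6 genes, as turning is what aligns the dye swap. On the TIP1 side alone, the 10 became 18 with 4 arrays as separate replicates, 17 with a dye term, 5 with equal scaling, 23 with robust moderation and 5 without the length trend, over all genes and over spans that are multiples of 3. Without the length trend the total was 153, and 144 (again 5 on the TIP1 side) when row names matched through synonyms were also left out; without such matches the general stress list had 28 of 34 members changed and 8 lists passed. Past the threshold were 8 lists, and 0 with an estimated correlation on the 4 arrays, which were not averaged by culture there. With rank-based camera 13 passed (7 of the 8 among them, without the hexose transporters). Without the length trend 10 passed (7 of the 8), and without 1 array 8 to 11. The mean correlation between arrays of 0.459 was 0.305 as Spearman's rho. With arrays paired as 1 with 4 and 2 with 3, the spread between culture means holds only the contrast of arrays 1 and 4 with arrays 2 and 3 (6.16% of the variance over genes, against 21.0% in the other pairing), by construction of the means; for the other settings the cause was not tested. Of the 67 named genes, 0 changed side under any of the settings run on them. For the pairings and for leaving out an array that result was fixed in advance, since these genes lay on 1 side on all 4 arrays. Without array 1, 26 of them lost the call, and without array 2, 20. Among genes named after their values were seen, PRM5, PST1 and DAK2 changed side without array 2 (means of -0.08, -0.07 and -0.01 toward the HSP12 side). PRM5 also did so without array 4 (-0.009), and GPD2 without array 1 (0.01 toward the HSP12 side). None of these genes was called. The median over spots was not run, since each reading frame has 1 row. No paired analysis between groups was possible because the arrays form 1 group, in which each array is itself a pair of treated and untreated RNA. Signal over background is unknown, so its limit on weak spots could not be assessed.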

Other observations

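The genes of this paragraph were chosen after their values were seen, and all but GPD2 lay on the HSP12 side. Of genes of glycerol metabolism, GPD1, glycerol phosphate dehydrogenase (2.23 ± 0.25, SD, n = 4), GPP2, glycerol phosphatase (1.19 ± 0.21), DAK1, dihydroxyacetone kinase (1.28 ± 0.22), GUT2, the mitochondrial dehydrogenase (1.25 ± 0.42), and GCY1, a glycerol dehydrogenase (0.93 ± 0.41), changed. Their relatives GPP1 (0.28 ± 0.25) and DAK2 (0.10 ± 0.29) and the glycerol kinase gene GUT1 (0.59 ± 0.86) did not pass the threshold, nor did GPD2, the other isoform of GPD1, with 0.08 ± 0.23 on the TIP1 side. YDL023C, a frame next to GPD1 with no RefSeq match, had 2.08 ± 0.18, and its spot may read GPD1 RNA, which was not tested. It was past the threshold in limma, as were the genes named next, and 20 of 20 members of the high osmolarity list lay on this side. Aldehyde dehydrogenase genes ALD3 (2.51 ± 0.33) and ALD4 (2.11 ± 0.48) changed, as did ARO10 (1.52 ± 0.29) and ARO9 (1.01 ± 0.12) of aromatic amino acid breakdown. SNZ3 and SNZ1, of vitamin B6 synthesis, had 1.37 ± 0.44 and 0.89 ± 0.51. CMK2, a calmodulin-dependent kinase, had 1.60 ± 0.28, and the calcineurin regulators RCN2 and RCN1 had 1.14 ± 0.23 and 0.85 ± 0.31. The changed genes were also called with the length trend removed, apart from YDL023C, which has no length. Of them GCY1 lost its call without array 1 or 2 (adjusted p = 0.130 and 0.125), and SNZ1 and RCN1 without array 1, 2 or 4 (0.0877 to 0.297).

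Members of the cell wall integrity list differed in size, with 6 of 23 called. PRM5 had 0.08 ± 0.46, PST1 0.12 ± 0.43 and PIR3 0.42 ± 0.19 on the HSP12 side, without a call (adjusted p = 0.941, 0.913 and 0.557), and were likewise chosen after their values were seen. CWP1, PUN1 and YPS1 of the same list had 1.83, 1.59 and 1.48 and were called. SED1, a wall protein and a called member with a mean of 1.35, had 2.01, 1.88 and 1.97 on arrays 1, 2 and 4, but lay on the opposite side on array 3 (mean 1.95 without it), and lost its call without array 1, 2 or 4 (adjusted p from 0.0802 to 0.536).

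Frames laid out as Ty elements, a short frame nested in a long one, differed between arrays. All 8 measured short frames were called on the HSP12 side, with medians of 0.79, 0.52, 4.59 and 2.26 on arrays 1 to 4. Of 12 long frames, 4 were called, and their medians on arrays 1, 2 and 4 were 0.77, -0.35 and -0.19, with array 3 furthest on the HSP12 side. The elements are near-identical, so these spots do not give independent values.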
